A study of Mus musculus with 6 samples.

How the data were processed

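Kidneys of mice with renal fibrosis driven by TGF-β1 were measured on 6 arrays, each taken as 1 animal, in 2 groups of 3 given by the labels. The groups were B6-TGFbeta (replicates 1, 2 and 3), named for the inbred C57BL/6 background, and CBAxB6-TGFbeta (replicates 4, 5 and 6), named for a background of CBA and B6. The labels also carry the words WT for the first group and KO for the second, but name no knocked-out gene, and these words were not used. The labels state that cohorts were littermates matched for age and sex. No age, sex, batch or scan day is given in the sources used here. The groups share no replicate numbers.

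The deposited table holds log2 intensities of an Affymetrix mouse gene array at the level of exon probe sets, 1 row per probe set. RMA and Partek are named in the submitters' processing notes, without versions or settings, so the background correction, the normalization and the genome build of the array annotation are not given in the sources used here. Array medians lay between 7.27 and 7.34 on the log2 scale. The distributions were similar but not identical, and the step that put the arrays on 1 scale is not stated. No coordinates are given because the genome build of the annotation is unknown.

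Of 241576 rows, 212097 carried 1 gene symbol, 4475 carried several and 25004 carried none in the annotation table. Rows with 1 symbol were combined into 20416 genes by Tukey's median polish over the rows of a gene, with a median of 8 rows per gene and 2292 genes resting on 1 row. Symbols are those of the array annotation. Among them 17621 were current symbols and 2742 were older names in a RefSeq gene table (assembly GRCm38.p6, used for names only), and 53 were in neither form.

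Differences were computed as CBAxB6-TGFbeta minus B6-TGFbeta with limma (version 3.58.1 in R 4.3.3) by a linear model with 1 group term, moderated variances and no other covariate, over all 6 arrays. The p-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. Errors of differences are standard errors of the moderated model. Values per group are means ± SD over 3 arrays. Depth has no meaning for arrays, and the number of arrays limits the precision.

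A set of 35 gene lists with 931 entries was fixed before the data were examined, and 883 entries matched a measured gene. Each list is described by the number of genes that passed, over all genes and adjusted over the list alone. The 34 lists with at least 5 measured genes were also tested by limma's camera with a preset correlation of 0.01 between genes, again with a correlation estimated per list, and by limma's fry, which asks whether the genes of a list move on balance one way. Genes named in the text follow a rule also fixed before the data were examined: Timp1 and Egr2, the genes of the title; the 12 largest differences in each direction among passing genes whose groups did not overlap, where unnamed transcripts count but need not be named; up to 4 passing members of each list with the smallest p, or up to 2 members as values where none passed; and the genes of the sex chromosome and strain lists. Other genes are marked where they were chosen after their values were seen, except Lcn2 and some markers of neighbouring tissues. The latter include Ucp1, Adipoq, Car3, Alb, Chgb and Dbh, which lie outside this rule.

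Rows that deviate from the rest of their gene were tested with limma's diffSplice in genes with at least 3 rows, which takes 1 variance per gene.

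The calculations were tested on simulated data for this comparison with 20416 genes, of which 200 were changed. At log2 changes of -2 and 2, 100% and 97.0% of the changed genes were recovered, at -1 and 1 66.7% and 70.6%, and at -0.5 and 0.5 12.1% and 2.94%. Of the 120 genes called there, 4 were unchanged. The row test recovered 90% and 94% of rows shifted by -2 and 2, but 778 of its 962 calls were unchanged rows, so no single row is named from its calls on real data, which are counted and serve to remove rows in 1 added alternative. A test that gives each row its own moderated variance was therefore added after seeing the data. It recovered 29% and 23% of the shifted rows, with 3 unchanged rows among 55 calls.

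The alternatives were a second quantile normalization, median centring, the mean or the brightest row in place of median polish, removal of the dimmer 50% of rows of each gene or the dimmest 25% of genes, trended and robust moderation, array weights, a linear model without moderation, other list tests, and each array left out in turn. Fits with replicate 3 as the only B6-TGFbeta array, and with deviating rows removed before the gene summary, were added after seeing the data. Rows with several symbols or none were left out of the gene analysis.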

Results

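Gene expression was measured in kidneys of mice with renal fibrosis driven by TGF-β1, a cytokine that promotes matrix deposition, on 2 genetic backgrounds. The B6-TGFbeta and CBAxB6-TGFbeta groups held 3 arrays each. Median intensities ran from 7.27 to 7.34 on the log2 scale. Across all probe sets, which are not independent replicates, arrays correlated at 0.965 to 0.971 within B6-TGFbeta and at 0.953 to 0.963 within CBAxB6-TGFbeta. Between the groups the correlations were 0.946 to 0.954. The comparison asks how the kidneys differ between backgrounds that the series title sets apart by their susceptibility to fibrosis, with Timp1 and Egr2 named in that title. All arrays carry TGFbeta in their labels, and none is from mice without it. A difference between the backgrounds before fibrosis and a different response to TGF-β1 therefore cannot be told apart. The words WT and KO of the labels follow the same split, so a genotype they may stand for cannot be separated from the background either.

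Both genes of the title were higher in CBAxB6-TGFbeta kidneys. The title may draw on these same arrays, so the p-values of both genes are not an independent test of it. Timp1, which encodes a secreted inhibitor of matrix metalloproteinases, had a log2 intensity of 6.12 ± 0.17 (SD, n = 3) in B6-TGFbeta and 9.002 ± 0.41 (SD, n = 3) in CBAxB6-TGFbeta, a log2 difference of 2.88 (SE 0.19) and 7.36-fold on the linear scale. Egr2, a zinc finger transcription factor of the early growth response family, had 7.68 ± 0.11 and 10.03 ± 0.62 (SD, n = 3 each), a log2 difference of 2.35 (SE 0.25) and 5.09-fold. Adjusted p was 0.000114 for Timp1 and 0.00108 for Egr2 in limma with Benjamini-Hochberg adjustment. All 3 CBAxB6-TGFbeta arrays lay above all 3 B6-TGFbeta arrays for both genes. The difference was positive in 6 of 6 Timp1 probe sets, from 1.39 to 4.02, and in 5 of 5 Egr2 probe sets, from 1.10 to 2.96. Timp1 missed the threshold without B6-TGFbeta replicate 1 or 3 (adjusted p 0.0530 and 0.0503), and Egr2 without B6-TGFbeta replicate 1, 2 or 3 or CBAxB6-TGFbeta replicate 5 (0.106, 0.0801, 0.0882 and 0.0792), while the log2 differences over all arrays left out in turn stayed at 2.65 to 3.04 and 1.97 to 2.70. Without moderation of the variances adjusted p was 0.0569 and 0.106, and with the brightest probe set of a gene alone Egr2 stood at 1.10 with an adjusted p of 0.0667.

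**Figure D1:**
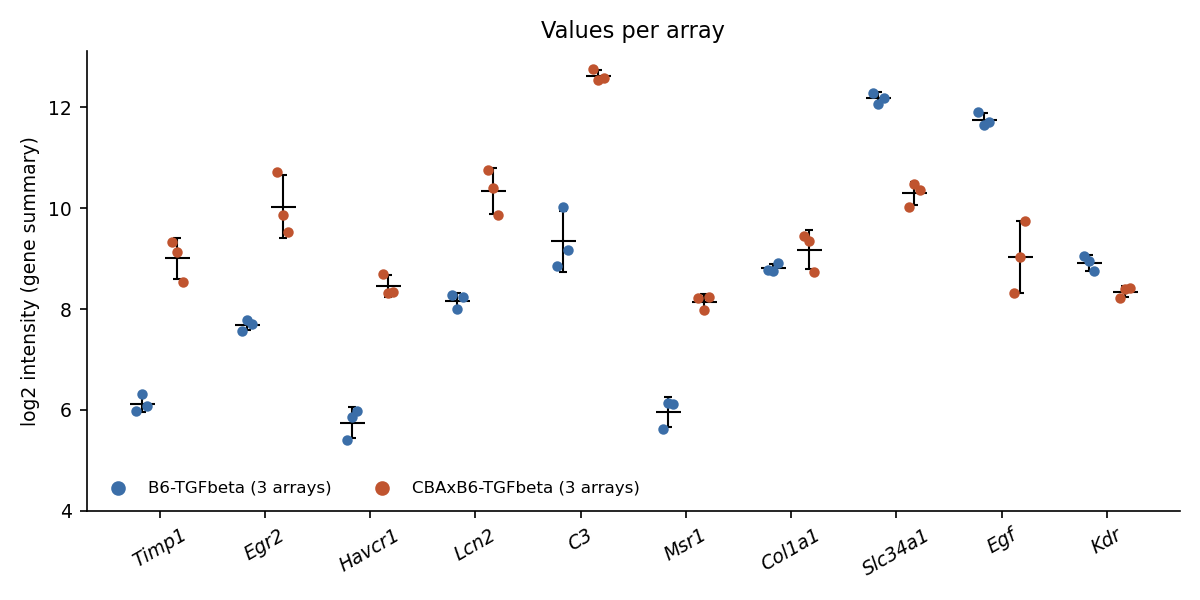
Log2 intensity of 10 genes in each of the 6 arrays, with B6-TGFbeta in blue, CBAxB6-TGFbeta in orange, and bars giving the mean ± SD of 3 arrays. Timp1 rises from 6.12 to 9.002 and Egr2 from 7.68 to 10.03, Slc34a1 falls from 12.17 to 10.29, and the Col1a1 values of the groups overlap.

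The largest named increases were in the fibrinogen chains Fgg (4.04, SE 0.15), Fgb (3.14, SE 0.26) and Fga (2.57, SE 0.11), the MHC class II gene H2-Ea, C3 of complement (3.28, SE 0.25), the keratin Krt20 (3.18, SE 0.20), the protease inhibitor Serpina3n (2.77, SE 0.25), Havcr1, which encodes the kidney injury molecule KIM-1 (2.70, SE 0.17), Abp1, an amine oxidase (2.64, SE 0.21), and the cytokine Il6 (2.59, SE 0.34). The unnamed transcript C130026I21Rik, on 1 probe set, was also among the largest (2.92, SE 0.43), as was Timp1, given above (2.88, SE 0.19). The largest named decreases were in Egf (-2.72, SE 0.29), Miox, which encodes the inositol-degrading oxygenase of the proximal tubule (-2.57, SE 0.25), C730048C13Rik, now the solute carrier gene Slc22a30 (-2.45, SE 0.50), Pfn3 (-2.34, SE 0.15), Abca13 (-2.14, SE 0.17), Hao2 (-2.02, SE 0.27), Pck1, a key enzyme of gluconeogenesis (-1.99, SE 0.21), Serpina1f (-1.97, SE 0.13), Ugt3a1 (-1.89, SE 0.24), the phosphate transporter Slc34a1 (-1.88, SE 0.13), the glucose transporter Slc5a2 (-1.88, SE 0.23) and Gpx6 (-1.87, SE 0.21). Abp1 rested on 5 probe sets, 80% of which moved upwards, and its brightest probe set alone gave -0.55. The brightest probe sets of Serpina3n and Slc34a1 gave 1.21 and -0.998, and that of Hao2 gave -1.10 and did not pass.

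Among 20416 genes, 1562 (7.65%) passed at an adjusted p under 0.05, 628 higher and 934 lower in CBAxB6-TGFbeta. Of these, 143 were at least 2-fold higher and 152 at least 2-fold lower. The groups did not overlap in any of the 1562 genes and did not overlap in 26.8% of all genes, where chance gives 10%. In the 1456 passing genes with at least 3 probe sets, the median share of probe sets that moved in the direction of the gene was 100%. Such agreement is partly built in, since the gene value summarises these same probe sets and the genes were selected by it. The number of passing genes fell to 59, 77 and 57 without B6-TGFbeta replicate 1, 2 and 3, to 269, 117 and 554 without CBAxB6-TGFbeta replicate 4, 5 and 6, and to 63 without moderation of the variances. More genes were lower than higher in these fits, but with the brightest probe set of each gene alone 335 were higher and 282 lower, and with replicate 3 as the only B6-TGFbeta array, a choice made after seeing the data, 25 were higher and 15 lower. Of the 114 named genes that passed, Ccl12, Cfi, Fga, Fgg, H2-Ea, Vcam1 and Vcan (7) passed under every gene-level alternative and 107 missed the threshold under at least 1. On the brightest probe set of each gene, 49 of the 114 missed it and 31 moved by more than 1.5 times.

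**Figure D2:**
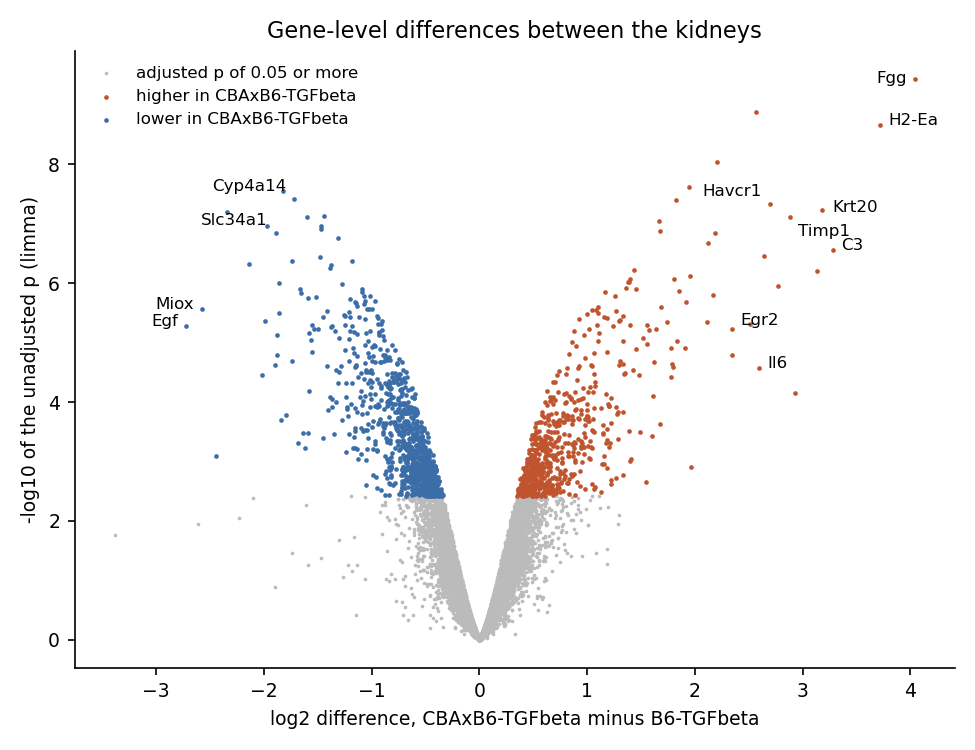
Each point is 1 of 20416 genes, with the log2 difference of CBAxB6-TGFbeta minus B6-TGFbeta on the x axis and the -log10 of the unadjusted limma p on the y axis. The 628 orange and 934 blue genes passed the adjusted threshold, with Fgg at 4.04 and Egf at -2.72.

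Of 32 measured tubular injury genes, 20 were higher, none was lower and 12 did not pass, with a median log2 difference of 0.94. Adjusted over the list alone, 24 passed. Besides Fgg, Fga and Havcr1, the adhesion molecule Vcam1 was higher (1.94, SE 0.11). The list passed camera with the preset correlation, with an adjusted p = 0.128 with an estimated correlation. Of 38 proximal tubule genes, 26 were lower, 12 did not pass and none was higher, with a median of -0.83, and adjusted over the list alone 30 were lower and 1 higher. The dicarboxylate transporter Slc13a3 (-1.86, SE 0.16) and G6pc, which releases glucose in gluconeogenesis (-1.45, SE 0.15), were lower beside Slc34a1 and Miox. The list passed camera, with an adjusted p = 0.151 with an estimated correlation. On the brightest probe set of each gene, 16 injury genes were higher and 10 proximal tubule genes lower, with medians of 0.95 and -0.72, and with each array left out in turn 5 to 16 and 1 to 18 passed.

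In the loop of Henle and distal tubule list, 12 of 21 genes were lower and 9 did not pass, 15 being lower when adjusted over the list alone, with a median of -0.58 (adjusted p = 0.0856 with an estimated correlation). Beside Egf, the thiazide-sensitive transporter Slc12a3 (-1.53, SE 0.17), Ppp1r1a (-1.20, SE 0.13) and the potassium channel Kcnj10 (-0.93, SE 0.10) were lower. In the collecting duct list, 13 of 26 genes were lower and 13 did not pass, 19 being lower when adjusted over the list alone, with a median of -0.47 (adjusted p = 0.0856 with an estimated correlation). The ammonia transporter Rhcg (-1.18, SE 0.14), the receptor gene Insrr (-0.92, SE 0.15) and the water channel Aqp3 (-1.09, SE 0.16) were among them. In the podocyte list, 5 of 25 genes were lower and 20 did not pass, with a median of -0.13, and adjusted over the list alone 7 were lower and 2 higher. Podxl (-0.64, SE 0.13) and the nephrin gene Nphs1 (-0.44, SE 0.10) were among the lower ones, and the list had an adjusted p = 0.328 with an estimated correlation. The preset call of the podocyte list was lost under 13 of 18 alternatives. In the endothelium list, 8 of 26 genes were lower and 18 did not pass, 16 being lower when adjusted over the list alone, with a median of -0.32 (adjusted p = 0.0856 with an estimated correlation). The VEGF receptor gene Kdr (-0.57, SE 0.11) and Icam2 (-0.48, SE 0.10) were lower. On the brightest probe set of each gene, 6 loop and distal tubule, 3 collecting duct, 1 podocyte and 0 endothelium genes were lower, with medians of -0.40, -0.41, -0.13 and -0.28. The brightest probe sets of Slc12a3 and Nphs1 gave -0.99 and -0.67, and that of Aqp3 gave -0.38 and did not pass.

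**Figure D3:**
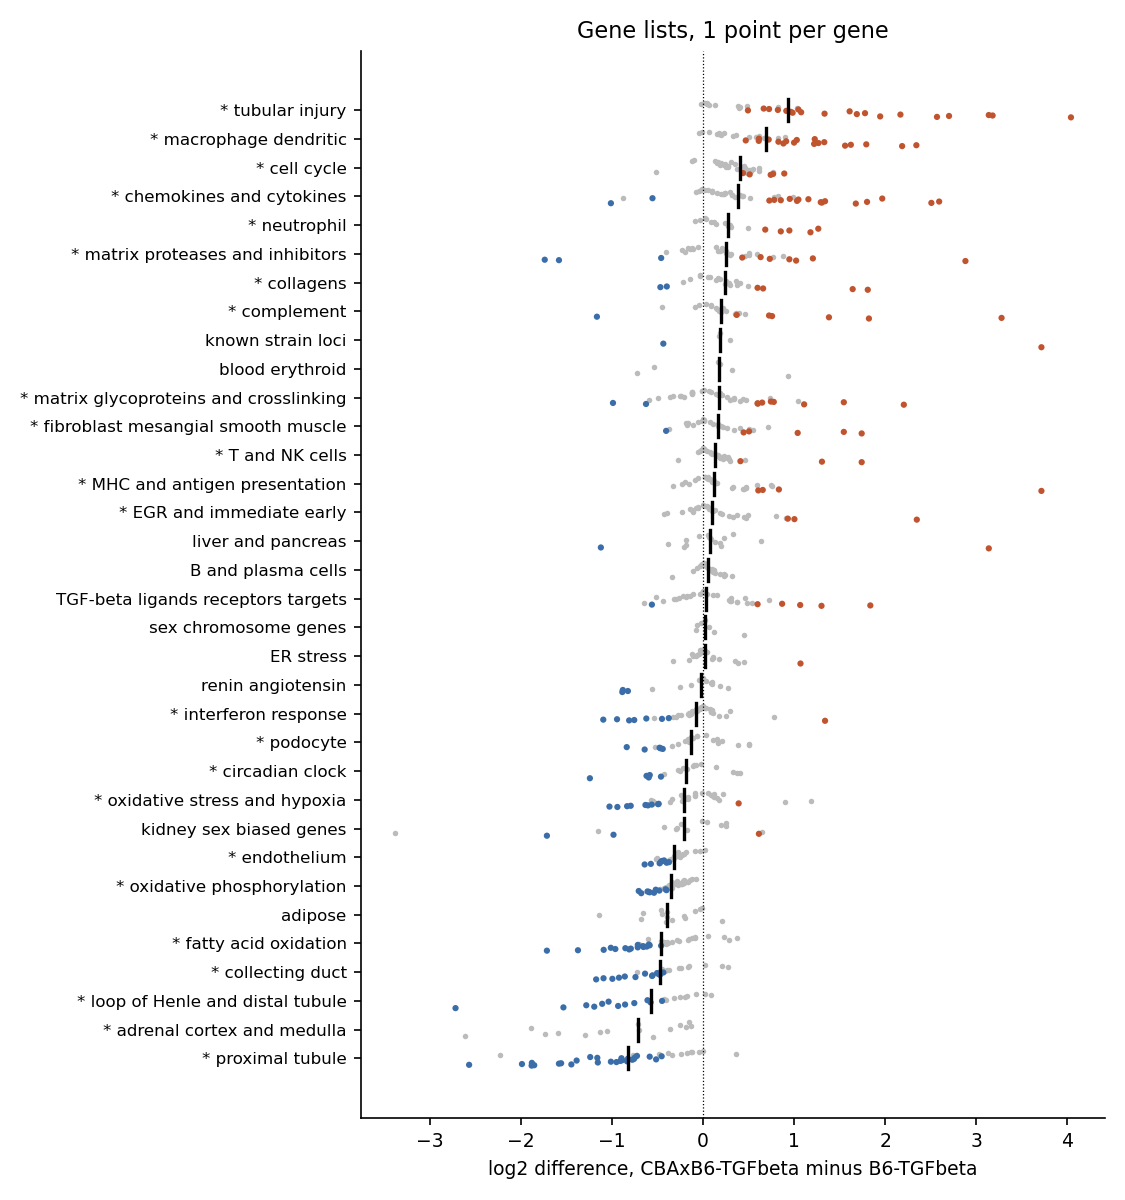
Log2 differences of CBAxB6-TGFbeta minus B6-TGFbeta for the genes of 34 fixed lists, 1 point per gene, with passing genes in orange (higher) or blue (lower), other genes in grey and the list median as a black bar. Stars mark the 24 lists that passed camera with the preset correlation, none of which passed with an estimated correlation, and the medians run from 0.94 for tubular injury to -0.83 for proximal tubule.

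Of 36 genes of fatty acid oxidation, 16 were lower and 20 did not pass, 25 being lower when adjusted over the list alone, with a median of -0.46 (adjusted p = 0.0856 with an estimated correlation). The fatty acid hydroxylase Cyp4a14 (-1.72, SE 0.10), the thiolase Acaa2 (-1.38, SE 0.11), Hadh (-1.09, SE 0.10) and Cpt2 of the carnitine shuttle (-0.81, SE 0.09) were examples. Of 34 genes of oxidative phosphorylation, 10 were lower and 24 did not pass, 16 being lower when adjusted over the list alone, with a median of -0.35 (adjusted p = 0.198 with an estimated correlation). Ndufb3 (-0.68, SE 0.10) of complex I and Sdha (-0.59, SE 0.10) of complex II were lower. B6-TGFbeta replicate 2 showed the brown fat gene Ucp1 at 10.93 on the log2 scale, against 5.13 to 6.22 in the other 5 arrays, and with replicate 3 as the only B6-TGFbeta array, a choice made after seeing the data, the medians were -0.41 for fatty acid oxidation and -0.25 for oxidative phosphorylation. In the oxidative stress and hypoxia list, 9 of 37 genes were lower, 1 was higher and 27 did not pass, and adjusted over the list alone 12 were lower and 2 higher (adjusted p = 0.0856 with an estimated correlation). Catalase (Cat, -0.94, SE 0.10) and Epas1, which encodes HIF-2α (-0.80, SE 0.11), were among the lower genes. On their brightest probe sets Sdha stood at -0.25 and Cat at -0.40, and neither passed. The counts on these probe sets were 8 lower and 1 higher for fatty acid oxidation, 1 lower for oxidative phosphorylation and 2 lower for oxidative stress and hypoxia.

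Matrix genes changed in part. Of 23 collagen genes, Col12a1 (1.81, SE 0.16), Col8a1 (1.64, SE 0.18), Col5a2 (0.66, SE 0.10) and Col3a1 (0.60, SE 0.11) were higher, 2 were lower and 17 did not pass, and adjusted over the list alone 7 were higher and 2 lower. On their brightest probe sets Col5a2 stood at 1.63 and passed and Col3a1 stood at 0.26 and did not. Col1a1, chosen after its value was seen, had a log2 difference of 0.36 (SE 0.17, adjusted p 0.266). The collagen list passed camera, with an adjusted p = 0.328 with an estimated correlation. Of 42 matrix glycoprotein and cross-linking genes, 8 were higher, 2 were lower and 32 did not pass, and adjusted over the list alone 17 were higher and 4 lower (adjusted p = 0.463 with an estimated correlation). Versican (Vcan, 2.20, SE 0.11), tenascin C (Tnc, 1.11, SE 0.12) and fibrillin 1 (Fbn1, 0.60, SE 0.10) were higher and Fbln5 was lower (-0.63, SE 0.10). Of 34 matrix proteases and inhibitors, 7 were higher, 3 were lower and 24 did not pass, and adjusted over the list alone 14 were higher and 3 lower (adjusted p = 0.203 with an estimated correlation). Beside Timp1, Adamts1 was higher (1.02, SE 0.11), and the brush border meprins Mep1a (-1.58, SE 0.17) and Mep1b (-1.74, SE 0.22) were lower. Of 29 fibroblast, mesangial and smooth muscle genes, 5 were higher, 1 was lower and 23 did not pass, and adjusted over the list alone 7 were higher and 2 lower (adjusted p = 0.328 with an estimated correlation). Thy1 (1.74, SE 0.18), which T cells also express, calponin (Cnn1, 1.04, SE 0.20) and lumican (Lum, 1.54, SE 0.37) were higher. Brightest probe sets gave 3 higher genes in each of the 4 lists, and 2 lower ones among the proteases and inhibitors alone.

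The TGF-β list of ligands, receptors and targets did not pass camera (adjusted p 0.0635). Of its 36 genes, 5 were higher, 1 was lower and 30 did not pass, and adjusted over the list alone 10 were higher and 2 lower. Inhba, a subunit of activin (1.30, SE 0.14), Ankrd1 (1.84, SE 0.21) and Ltbp2 (1.07, SE 0.13) were higher and Bmp7 was lower (-0.56, SE 0.11). On their brightest probe sets Inhba stood at 2.44 and passed, and Ankrd1 at 0.86 and Ltbp2 at -0.22 did not. Tgfb1 itself, chosen after its value was seen, had a log2 difference of 0.48 (SE 0.13, adjusted p 0.0609). Of 30 EGR family and immediate early genes, Egr2, Klf6 (1.00, SE 0.17) and Atf3 (0.93, SE 0.21, and 1.85 on its brightest probe set, which passed) were higher and 27 did not pass, 4 being higher when adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Egr1, chosen after its value was seen, had a log2 difference of 0.80 (SE 0.31, adjusted p 0.174). Brightest probe sets gave 2 higher genes in the TGF-β list and 3 in the EGR list, and without the dimmer 50% of rows both lists had 7.

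Of 34 macrophage and dendritic cell genes, 18 were higher and 16 did not pass, 24 being higher when adjusted over the list alone, with a median of 0.69 (adjusted p = 0.161 with an estimated correlation). The scavenger receptor Msr1 (2.19, SE 0.15) and the mannose receptor Mrc1 (1.56, SE 0.18) were examples. So were the chemokine receptor Ccr2 (2.34, SE 0.29) and the integrin Itgam (1.62, SE 0.20). The brightest probe sets of Mrc1 and Itgam gave 0.92 and 2.93 and passed. Over 17 alternatives, Msr1, Mrc1, Ccr2 and Itgam missed the threshold in 2, 8, 7 and 6. Of 17 neutrophil genes, 5 were higher and 12 did not pass, 7 being higher when adjusted over the list alone (adjusted p = 0.166 with an estimated correlation), with Hdc at 1.18 (SE 0.17) and Mmp8 at 0.95 (SE 0.14). Low intensities limit Mmp8, with means of 4.69 in B6-TGFbeta and 5.64 in CBAxB6-TGFbeta. Of 44 chemokines and cytokines, 15 were higher, 2 were lower and 27 did not pass, and adjusted over the list alone 19 were higher and 3 lower (adjusted p = 0.0856 with an estimated correlation). The monocyte chemoattractants Ccl2 (2.51, SE 0.27) and Ccl12 (1.68, SE 0.12) were higher and Cxcl12 was lower (-1.01, SE 0.09). With its brightest probe set alone, Ccl2 stood at 0.28 and did not pass. Of 25 complement genes, 6 were higher, 1 was lower and 18 did not pass, and adjusted over the list alone 8 were higher and 1 lower (adjusted p = 0.166 with an estimated correlation). Beside C3, Cfi (1.82, SE 0.11) and the receptor C3ar1 (1.38, SE 0.12) were higher and the membrane inhibitor Cd59a was lower (-1.17, SE 0.14). Brightest probe sets gave 9 higher macrophage and dendritic cell genes, 2 neutrophil genes, 7 chemokines and cytokines (besides 1 lower) and 3 complement genes.

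Of 30 T and NK cell genes, Thy1, Ccl5 (1.30, SE 0.16) and Cd2 (0.41, SE 0.11) were higher and 27 did not pass, also 3 being higher when adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). With its brightest probe set alone, Ccl5 stood at 0.07 and Cd2 at 0.61, neither passing, and Cd2 missed the threshold under 12 of 16 alternatives. Of 21 B and plasma cell genes none passed in limma over all genes or adjusted over the list alone, with Blnk at -0.34 (SE 0.10) and Cd79a at 0.32 (SE 0.14). Of 31 MHC and antigen presentation genes, 4 were higher and 27 did not pass, with a median of 0.12. Adjusted over the list alone 11 were higher, and the list had an adjusted p = 0.203 with an estimated correlation. The 4 were H2-Ea, which C57BL/6 mice do not express, H2-Aa (0.83, SE 0.21), H2-DMb2 (0.65, SE 0.14) and H2-M2 (0.61, SE 0.12). H2-M2 stood at low intensities of 4.05 in B6-TGFbeta and 4.65 in CBAxB6-TGFbeta. Of 39 interferon response genes, 7 were lower, 1 was higher and 31 did not pass, and adjusted over the list alone 8 were lower and 2 higher (adjusted p = 0.457 with an estimated correlation), and the preset call of the list was lost under 6 of 18 alternatives. Ifi44 (-1.10, SE 0.19), Xaf1 (-0.81, SE 0.13) and Rtp4 (-0.76, SE 0.13) were lower, and the chemokine Cxcl10 was higher (1.34, SE 0.18). The brightest probe sets of H2-Aa and Xaf1 gave 0.13 and -0.48 and did not pass. On brightest probe sets, 2 T and NK cell, 0 B and plasma cell and 2 MHC genes were higher, and among interferon response genes 2 were lower and 1 higher.

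Of 34 cell cycle genes, 5 were higher and 29 did not pass, with a median of 0.40, and adjusted over the list alone 16 were higher and 1 lower (adjusted p = 0.226 with an estimated correlation). The replication licensing gene Mcm4 (0.74, SE 0.10) and the mitotic checkpoint gene Bub1 (0.89, SE 0.19) were higher. Of 19 circadian clock genes, 5 were lower and 14 did not pass, and adjusted over the list alone 6 were lower and 2 higher (adjusted p = 0.213 with an estimated correlation). Hlf (-1.24, SE 0.13), Tef (-0.60, SE 0.11), Per3 (-0.46, SE 0.09) and Per2 (-0.62, SE 0.13) were lower, and the hour of collection is not given in the sources used here. Of 15 renin-angiotensin genes, Ace (-0.89, SE 0.10), Kng2 (-0.83, SE 0.12) and the mineralocorticoid receptor Nr3c2 (-0.88, SE 0.16) were lower and 12 did not pass, 4 being lower when adjusted over the list alone, and the list did not pass camera (adjusted p 0.0684). Of 22 ER stress genes, Asns (1.07, SE 0.26) was higher and 21 did not pass, and none passed when adjusted over the list alone. Bub1 stood at 1.51 and Tef at -0.35 on their brightest probe sets, and neither passed. Those probe sets gave 4 higher cell cycle, 1 lower clock, 3 lower renin-angiotensin and 0 ER stress genes, and without the dimmer 50% of rows 10 cell cycle genes were higher.

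Several lists checked the labels and the tissue. The Y-linked Kdm5d stood at 8.61 ± 0.08 and 8.72 ± 0.05 (SD, n = 3 each) in B6-TGFbeta and CBAxB6-TGFbeta and Xist at 4.47 ± 0.22 and 4.41 ± 0.16 (SD, n = 3 each). None of the 7 sex chromosome genes passed in limma, over all genes or adjusted over the list alone, the differences of Eif2s3y, Kdm5c, Uty, Kdm6a and Eif2s3x being 0.45, -0.08, 0.07, -0.02 and 0.02. Among 16 genes that differ between male and female kidneys, Timd2 was higher (0.61, SE 0.11), Cyp4a14 and Kap (-0.98, SE 0.17) were lower and 13 did not pass, with the same counts adjusted over the list alone. Of 5 genes at loci known to differ between inbred strains, H2-Ea, which C57BL/6 mice do not express, stood at 5.24 ± 0.06 in B6-TGFbeta and 8.96 ± 0.36 (SD, n = 3 each) in CBAxB6-TGFbeta and was higher in 5 of 5 probe sets. Nnt, part of which is deleted in the C57BL/6J substrain, was lower in CBAxB6-TGFbeta (-0.44, SE 0.11). It was lower in 17 of 20 probe sets, and the highest difference of a probe set was 0.52. These values gave no sign of that deletion in B6-TGFbeta. Glo1, Naip5 and Hc had differences of 0.30, 0.17 and 0.18 and did not pass, with the same counts adjusted over the list alone. On their brightest probe sets Timd2 stood at 1.61 and passed, and Kap at -0.61 and Nnt at -0.07 did not.

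Markers of neighbouring tissues differed between arrays of the same group. The 5 adrenal cortex genes Star, Cyp11b1, Cyp11a1, Cyp21a1 and Hsd3b1 were chosen after the values were seen. Their mean log2 intensity was 6.87, 8.79 and 5.48 in B6-TGFbeta replicates 1, 2 and 3. It was 5.36, 5.45 and 5.30 in CBAxB6-TGFbeta replicates 4, 5 and 6. Of the cortex genes left out, Mc2r, Nr5a1 and Cyp11b2 were higher in B6-TGFbeta replicate 1 than in replicate 3. Hsd3b6 (5.26 against 5.47) and Cyp17a1 (4.923 against 5.045) were lower there. None of the 15 adrenal genes passed in limma, also not adjusted over the list alone, with Star at -2.61 (SE 0.83) and Hsd3b6 at -0.55 (SE 0.16). The adrenal list passed camera downwards, with an adjusted p = 0.376 with an estimated correlation. None of 15 adipose genes passed over all genes or over the list alone, with Fabp4 at -0.40 (SE 0.24) and Pparg at 0.20 (SE 0.14), and Adipoq stood at 8.57 in B6-TGFbeta replicate 2. CBAxB6-TGFbeta replicate 4 showed a smaller fat signal, with Adipoq at 6.58 against 4.88 to 5.00 in the other 4 arrays, and Car3 at 8.73 against 6.10 to 7.42. Of 17 liver and pancreas genes, Fgb was higher, Apob was lower (-1.12, SE 0.23, and -0.59 on its brightest probe set, which did not pass) and 15 did not pass, with the same counts adjusted over the list alone. Alb stood at 9.45 in B6-TGFbeta replicate 2 and 10.94 in CBAxB6-TGFbeta replicate 6, and at 6.00 to 6.29 in the other 4 arrays. None of 6 erythroid genes passed over all genes, while adjusted over the list alone 2 were higher and 2 lower. Hbb-b1 stood at 0.94 (SE 0.27) and Slc4a1, which is also in the collecting duct list, at -0.73 (SE 0.21).

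**Figure D4:**
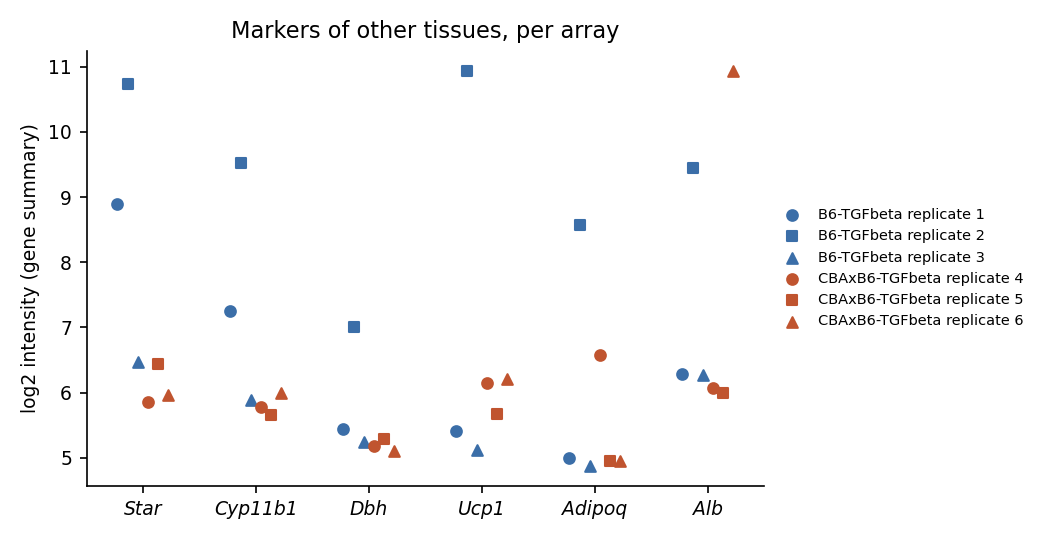
Log2 intensity of adrenal (Star, Cyp11b1, Dbh), fat (Ucp1, Adipoq) and liver (Alb) genes in each of the 6 arrays, 1 symbol per array. B6-TGFbeta replicate 2 stands at 10.74 for Star and 10.93 for Ucp1, and CBAxB6-TGFbeta replicate 6 at 10.94 for Alb.

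In the list tests, 24 of 34 lists passed camera with the preset correlation, 13 upwards and 11 downwards. None passed with an estimated correlation, where 9 had an unadjusted p under 0.05, and 19 passed fry. Another split of the same arrays gave an absolute median at least as large in 6 of the 24 lists: complement (0.20, other split 0.22), EGR family and immediate early (0.10, 0.17), fibroblast, mesangial and smooth muscle (0.16, 0.20), MHC (0.12, 0.13), interferon response (-0.08, 0.15) and adrenal (-0.71, 0.93). Within genes, diffSplice called 1164 of 207383 probe sets as deviating from the rest of their gene, 695 lower and 469 higher in CBAxB6-TGFbeta. With each probe set given its own variance, an alternative added after seeing the data, 1 probe set passed, a higher one in Sycp1, a gene chosen after its value was seen, with 16221 at an unadjusted p under 0.05.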

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

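Apart from the splits of the arrays, the neighbouring-tissue test of the nephron pattern and the number of deviating rows in other splits, the tests in this part were chosen after the result was seen. Groups of 3 were not tested for outlying arrays.

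Signals also appeared in rows that no test above used. In limma over all rows, 44 rows without a gene symbol and 34 rows with several symbols differed between the groups, which is 0.176% and 0.760% of such rows, against 0.572% of the rows with 1 symbol.

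There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, and the real split gave the highest count in each case (1 of 10 splits). The real split gave 1562 genes and the highest of the other splits 0, with 1159 genes there at an unadjusted p under 0.05. For lists called by camera with the preset correlation the counts were 24 and 22, and for deviating probe sets 1164 and 374. The other 9 splits gave 7 to 22 lists, so the number of list calls alone hardly sets the real split apart. Each of these splits mixes both groups on both sides. Part of the group difference thus stays in its comparison and part widens its spread. The counts of the other splits, for genes as for lists, therefore do not show what arrays without a group difference would give.

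The first pattern is that nephron markers were lower while injury and macrophage markers were higher in CBAxB6-TGFbeta. A lower share of proximal tubule cells alone would raise the markers of the other resident cell types, and the median of the loop and distal tubule, collecting duct, podocyte and endothelium markers was -0.37 (95% bootstrap interval -0.44 to -0.26, too narrow because it takes correlated genes as independent), while the means of these markers lay at 8.764 to 8.835 in the B6-TGFbeta arrays and at 8.376 to 8.434 in the CBAxB6-TGFbeta arrays. Dilution of all resident cells alike would lower podocyte and endothelium markers as much as proximal tubule markers, and their medians differed by 0.58 (0.40 to 0.81, with the same limit), the mean of the former minus that of the latter being -1.82 to -1.68 in the B6-TGFbeta arrays and -1.33 to -0.71 in the CBAxB6-TGFbeta arrays. Sequence variants under single probe sets would move a part of the probe sets of a gene, and over all 101 measured genes of the proximal tubule, injury and macrophage lists with at least 3 probe sets, whether they passed or not, the median share of probe sets in the direction of the list was 100%, while against B6-TGFbeta replicate 3 alone, the array of that group without adrenal or fat signal, the proximal tubule median was -0.85 (-1.05 to -0.53, with the same limit). The dilution comparison takes intensities to respond alike at all levels. In the B6-TGFbeta arrays proximal tubule markers averaged 10.35 to 10.5, podocyte markers 8.80 to 8.84 and endothelium markers 8.58 to 8.6. Whether log2 differences shrink at lower levels was not tested, so dilution also stays open. A biological difference between the backgrounds was not tested and stays open, as does one behind the label words WT and KO. Unequal loss of cell types and lower expression per cell stay open too. So does the day of collection, which is not given in the sources used here.

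The second pattern is the adrenal signal of B6-TGFbeta replicates 1 and 2. A strain difference in adrenal gene expression would also show in B6-TGFbeta replicate 3, whose cortex mean lay 0.11 above the CBAxB6-TGFbeta mean, while replicates 1 and 2 lay 1.47 and 3.40 above the mean of the other 4 arrays. In replicate 2 the 5 medulla genes rose as well, by 2.26 over the other 4 arrays, with Chgb at 11.21, which is consistent with adrenal tissue on that kidney. In replicate 1 the medulla genes stood 0.14 higher, where the SD of the other 4 arrays was 0.05, so a piece of cortex and another source cannot be told apart there, since cortex can be attached without medulla.

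The third pattern is that deviating probe sets were more often lower than higher in CBAxB6-TGFbeta. Sequence variants of CBA under probes designed on another strain may lower the signal of single probe sets, and 64.4% (exact binomial interval 61.0% to 67.7%, probe sets taken as independent) of deviating probe sets in genes that did not pass as a whole were lower. Over all genes 59.7% were lower in the real split, and another split of the arrays reached 75.4%. That split mixes both groups on each side and keeps a part of the group difference. It therefore cannot decide whether the imbalance comes from the strain, and the imbalance alone does not settle it. The other splits gave at most 374 deviating probe sets. The simulated data gave 387 lower and 391 higher false calls, and which probe sets cover variants was not analysed here.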

How the results depend on the processing

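The alternatives with replicate 3 as the only B6-TGFbeta array, with deviating rows removed and with a variance per row were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Leaving out each array in turn gave 57 to 554 passing genes (21 to 219 higher, 36 to 335 lower), Timp1 at 2.65 to 3.04, Egr2 at 1.97 to 2.70, 21 to 24 lists, and 425 to 1648 deviating rows (233 to 1046 lower, 192 to 604 higher). These fits have fewer arrays, and the estimated prior degrees of freedom fell from 5.21 to between 1.78 and 1.91.

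The brightest row of a gene gave 617 genes (335 higher, 282 lower, 54.3% higher against 40.2% with all rows), of which 439 were among the 1562, with Egr2 at 1.10, Abp1 at -0.55 and Ltbp2 at -0.22. The linear model without moderation gave 63 genes (23 higher, 40 lower), with Timp1 at 2.88 and Egr2 at 2.35 no longer past the threshold. Replicate 3 as the only B6-TGFbeta array gave 40 genes (25 higher, 15 lower, 62.5% higher), 39 of them among the 1562, with Egr2 at 2.38 no longer past the threshold and the median of the adipose list at 0.14. That lone array is assumed to vary like the CBAxB6-TGFbeta arrays, whose spread, moderated over genes, sets these tests. Array weights gave 974 higher genes. With a correlation estimated per list 0 lists passed camera, and 19 passed fry. Without the dimmer 50% of rows, 497 rows deviated (306 lower, 191 higher), and with a variance per row 1 did (0 lower, 1 higher). The causes were not tested.

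Median centring gave 47.9% higher genes, a second quantile normalization 44.4%, and neither moved the median over all genes by more than 0.1. Under the other alternatives the counts of passing genes and of passing lists stayed within a ratio of 1.5. The counts within single lists moved more. Leaving out single arrays also lowered the counts of the tubular injury and proximal tubule lists, with the ranges given above. Without the dimmer 50% of rows, higher cell cycle genes went from 5 to 10, higher EGR family and immediate early genes from 3 to 7, lower podocyte genes from 5 to 2 and higher neutrophil genes from 5 to 2, and array weights gave 13 higher cell cycle genes. Among the named genes, 1488 values under an alternative kept their direction and side of the threshold, 733 missed the threshold, 3 passed it anew and 2 reversed. The signal over background of single rows is not known, which limits what the dimmest genes show.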

Other observations

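The gene families below were chosen by symbol after seeing the data and were tested by Fisher's exact test among the brighter 75% of genes, with Benjamini-Hochberg adjustment over 50 tests, and genes are not independent replicates. Solute carriers were lower in 70 of 298 genes (23.5%, against 5.59% of the other genes, adjusted p 2.87e-22), including the bile acid transporter Slc10a1 (-1.86, SE 0.19), the neutral amino acid transporter Slc6a19 (-1.56, SE 0.18) and the organic anion transporter Slc22a8 (-1.39, SE 0.21). In the same family 8 genes were higher (adjusted p 0.735), among them Slc34a2 (1.07, SE 0.19), a phosphate transporter related to Slc34a1. Genes named as acyl-CoA dehydrogenases, synthetases and thioesterases were lower in 13 of 36 cases (adjusted p 1.68e-06), aldehyde dehydrogenases in 7 of 18 (adjusted p 0.000453), glutathione S-transferases in 6 of 17 (adjusted p 0.00216), cytochrome P450 genes in 9 of 41 (adjusted p 0.00344) and vacuolar ATPase subunits in 5 of 21 (adjusted p 0.0239). Among aldehyde dehydrogenases, 1 gene was higher, Aldh1a2, which makes retinoic acid (1.44, SE 0.12).

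Serpins were higher in 8 of 24 genes (33.3%, against 3.59% of the other genes, adjusted p 2.13e-05) and lower in 3 (12.5%, against 5.93%, adjusted p 0.388), including Serpina1f. Annexins were higher in 5 of 11 (adjusted p 0.000301), with Anxa1 at 0.98 (SE 0.12) and Anxa3 at 0.96 (SE 0.14), and integrins in 6 of 26 (adjusted p 0.00216), with Itga2 at 1.16 (SE 0.12). C-type lectins were higher in 4 of 16 genes (adjusted p 0.0101) and lower in 1, Clec2h (-1.15, SE 0.21). Of 7 caspases, Casp4 (1.55, SE 0.16) and Casp12 (0.97, SE 0.11) were higher, and the family did not pass (adjusted p 0.0722). Among S100 genes 3 of 10 were higher (adjusted p 0.0198), with S100a6 at 1.61 (SE 0.24), while the calcium-binding gene S100g of the distal nephron was lower (-1.67, SE 0.15). Zinc finger genes were less often higher than other genes, in 1 of 277 cases (0.361%, against 3.70% of the other genes, adjusted p 0.00494), while the 8 lower ones (2.89%, against 5.99%) did not pass as a family (adjusted p 0.0785).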
